A study of Mus musculus with 8 samples.

How the data were processed

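Gene expression was measured by RNA sequencing in 8 libraries of cells sorted by fluorescence, labelled as non-vascular smooth muscle cells, from mouse bladder (3 libraries), intestine (3 libraries) and lung (2 libraries). Per the labels, every mouse carried Cspg4-Dre, Acta2-CreERT and a GFP reporter at the Rosa26 locus, and tamoxifen was injected into the peritoneum at 0.75 mg per 10 g of body weight for 3 days, from a 20 mg/mL solution in corn oil. Dre and Cre are recombinases, and tamoxifen activates the CreERT form. RNA was purified with the miRNeasy micro kit and DNase, and at most 10 ng of total RNA went into the SMART-Seq v4 kit, per the labels' protocols. That kit amplifies full-length cDNA from little RNA and does not mark the strand, so reads of a gene and of an overlapping or antisense gene cannot be told apart.

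The deposited table lists 21649 genes with their coordinates. The submitters' processing notes name Trimmomatic 0.39, STAR 2.7.10a, Picard 3.0.0, featureCounts 2.0.4, DESeq2 1.36.0 and the genome build mm39, without saying what each did or in which order. The annotation release, the strand setting of the counting and any filter are not given in the sources used here. The unit of the deposited values was treated as a score: whole numbers with the spacing of read counts multiplied by a constant per library and then rounded. In bladder libraries 1, 2 and 3, 9, 8 and 4 of the whole values from 1 to 40 never occurred. In the intestine and lung libraries evenly spaced values were over-represented. The median ratio of each library to the geometric mean over genes was 1.01 in every library. These features were read from the values. The value of 1 read, estimated from this spacing, was 1.27, 1.25 and 1.10 in the bladder libraries, 0.920, 0.868 and 0.957 in the intestine libraries, and 0.822 and 0.865 in the lung libraries. Dividing by it gave reconstructed read counts, which in simulated libraries were at most 1 read from the true count. They were used for depth, for reads per nt and in alternatives.

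Depth was 9.72, 9.92 and 10.96 M reconstructed reads in the bladder libraries, 12.54, 13.19 and 12.03 M in the intestine libraries, and 13.62 and 12.67 M in the lung libraries. A gene without reads could have had up to 3, which is 2.47 to 3.81 in normalized value depending on the library. A fold against a tissue whose libraries were all at 0 was computed against the mean of these per-library floors and is given as a lower bound. Floors cover counting error only, and amplified reads without molecular identifiers are not independent molecules. Exon lengths for reads per nt came from GENCODE M21, which covers 96.8% of the gene IDs and is built on another genome assembly, so none of its coordinates were used. Coordinates in the text are those of the deposited table, build mm39, and span the whole annotated gene.

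The test fixed before the data were examined was a count test. Because the table holds normalized values, its stated fallback was used: limma with an intensity trend on log2(value + 1), all 8 libraries in 1 fit with a mean per tissue. The filter was set once the unit was known, in place of the count filter named before, and kept genes with a value of at least 10 in at least 2 libraries. That left 18097 genes, and 3552 were not tested. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. Genes with a Benjamini-Hochberg adjusted p under 0.05 were counted as higher or lower. A gene was counted as enriched in a tissue when it was higher there than in both other tissues, with the larger of the 2 p-values adjusted. Nothing in the labels says that the libraries came from separate mice, so p-values measure only the spread between these libraries, which may be technical.

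Named genes followed a rule fixed before the data were examined. Per pair of tissues and direction it took the 6 genes of largest absolute fold change that passed the test, had non-overlapping libraries and at least 10 ppm of the summed values in each library of the higher tissue, leaving out predicted genes and pseudogenes. Per tissue it took the 8 most enriched genes under the same conditions. It took Acta2, Cspg4 and Myh11 in each pair, up to 4 members per gene list and pair with the smallest p, and up to 2 abundant members that moved against the rest or of lists with none past the threshold. Some genes that met the rule are not reported. The 43 lists were fixed at the same time and cover muscle, developmental, signalling, metabolic and stress genes and markers of other cell types. They share members, so lists that move together partly count the same genes. Also in another list were 7 of 22 vascular smooth muscle and pericyte genes, 10 of 26 fibroblast genes and 11 of 15 airway smooth muscle genes. The mitochondrially encoded list had 0 genes in the table, and 42 lists were tested in 3 pairs with camera (preset correlation of 0.01), camera with an estimated correlation, and fry, on log2(value + 1), with adjustment over the 126 tests. Members past the threshold were counted over all genes tested and adjusted over the list alone.

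The test was checked on simulated intestine and bladder libraries of 17439 genes. It found 85% of 100 genes changed 2-fold and 100% of 100 genes changed 4-fold, and 5.13% of its 195 calls were genes that had not been changed. The alternatives chosen before the data were examined were upper-quartile scaling, limma-voom on the reconstructed reads, no filter and a stricter filter, a fold threshold of 1 on the log2 scale, pseudocounts of 0.1 and 5, robust estimation, a fit of only the tissues compared, a replicate block, leaving out ribosomal protein and haemoglobin genes, and leaving out each library. Chosen after seeing the data were the deposited scaling undone, scaling to equal totals, quantile normalization, scaling from genes under 0.3 reads per nt, and leaving out genes with a mean of at least 1 read per nt. Computation used R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6 and matplotlib 3.10.9.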

Results

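RNA of cells sorted as non-vascular smooth muscle cells, per the labels, was compared between 3 mouse organs, with 3 bladder, 3 intestine and 2 lung libraries. The libraries held 9.72 to 13.62 M reconstructed reads, with fewer in bladder than in the other organs, and 19206 to 20357 genes above 0. Values are normalized read counts, given as mean ± SD over the libraries of a tissue. Log2 values between libraries of 1 tissue correlated across genes at 0.967 to 0.975, against 0.798 to 0.805 between bladder and intestine, 0.872 to 0.877 between bladder and lung, and 0.790 to 0.804 between intestine and lung (genes are not independent replicates). Replicates differed by more than counting noise, with a chi-square per gene of 5.01 to 6.63 in bladder, 6.01 to 8.34 in intestine and 26.7 between the lung libraries. The first principal component held 59.6% of the variance and the second 27.3%.

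**Figure D1:**
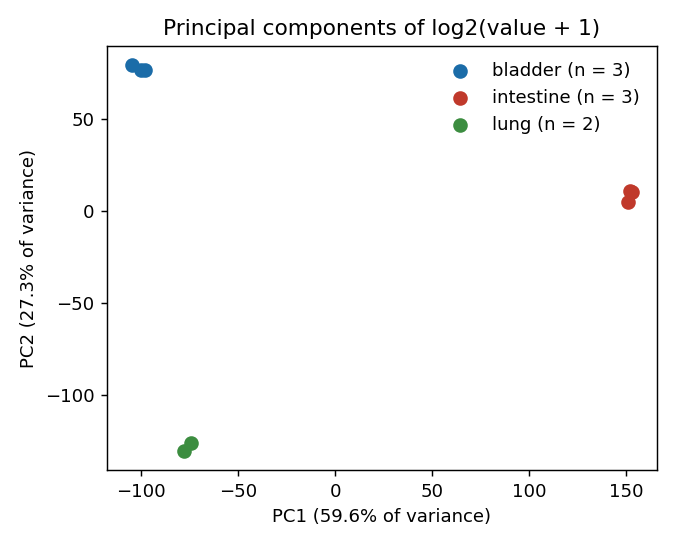
Principal components of log2(value + 1) over the 8 libraries, with one point per library coloured by tissue and the share of variance on each axis (59.6% and 27.3%). The libraries of each tissue lie together and the tissues lie apart.

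Of the genes that drive the recombinases, Acta2, which encodes smooth muscle actin (chromosome 19, 34218490 to 34232990), was at 2602 ± 308 in bladder, 2643 ± 214 in intestine and 2674.5 ± 62.9 in lung. It did not pass the test in any pair (limma, Benjamini-Hochberg adjusted p = 0.829, 0.766 and 0.899). Acta2 had 0.928 to 1.51 reads per nt of exon, a density at which reads rose less than depth. Cspg4, which encodes the NG2 proteoglycan of pericytes (chromosome 9, 56772317 to 56807154), was at 412 ± 23.4 in bladder, 4402 ± 200.5 in intestine and 4401 ± 503 in lung. Its log2 difference from bladder was 3.41 (SE 0.08) in intestine and 3.41 (SE 0.09) in lung, with limma adjusted p of 5.43e-08 and 5.44e-08 after Benjamini-Hochberg. Myh11, the smooth muscle myosin heavy chain (chromosome 16, 14012399 to 14109236), was at 5041 ± 921 in bladder, 11954 ± 546 in intestine and 10586 ± 295 in lung. It had 0.465 to 1.73 reads per nt, which reaches the same range. Summed over the list, fibroblast genes held 11771 ± 623 ppm of the values in bladder, 8444 ± 353 in intestine and 6887 ± 567 in lung, and contractile genes held 5424 ± 339, 8992 ± 319 and 9764 ± 764. Of these, 12 of 26 fibroblast and 6 of 36 contractile genes had a mean of at least 1 read per nt, where reads rose less than depth. The sums therefore do not compare the amounts of fibroblast and muscle RNA. Fibroblast genes were read in every library, and the labels' cell identity is not assumed for all RNA in the libraries.

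In limma's F test 11390 of 18097 genes differed among the 3 tissues. Genes near the upper end of read density moved together: 339 genes with a mean of at least 1 read per nt had a median log2 difference from bladder of -0.40 (SD 0.67) in intestine and -0.42 (SD 0.78) in lung, close to the scaling shift between the libraries of -0.40 and -0.51. Small negative differences of abundant genes stand beside that value throughout. Undoing the deposited scaling removes the correction for depth and moves most genes of a pair by nearly the same amount. List counts with it undone therefore show which lists rest on small differences, and are no estimate at equal depth. With it undone the median of all tested genes moved from 0.06 to 0.45 for intestine minus bladder and from 0 to 0.48 for lung minus bladder. Equal totals gave 0.15 and 0.12, and quantile normalization gave -0.15 for intestine minus bladder and 0.18 for lung minus intestine. Counts of list members are over all genes tested, and the count adjusted over the list alone was the same unless it is given.

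**Figure D2:**
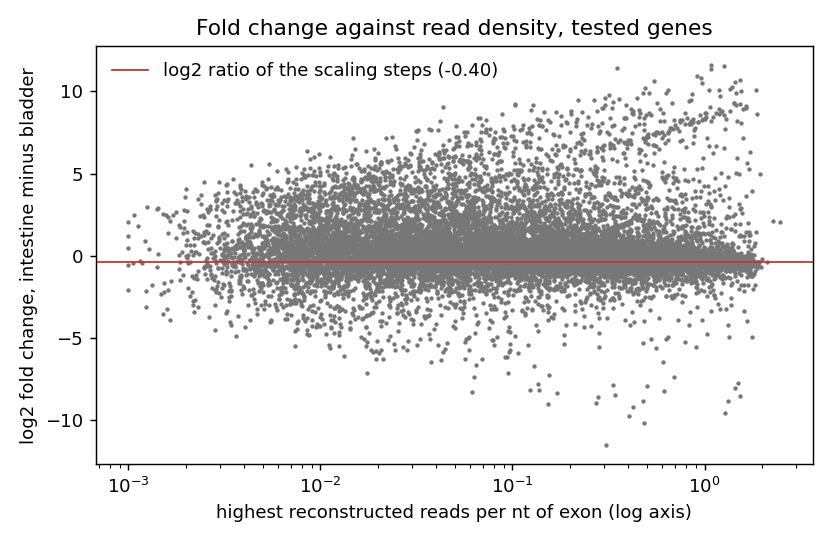
Log2 fold change of intestine minus bladder for each tested gene against its highest reconstructed reads per nt of exon over the 8 libraries (log axis), with one point per gene. The line marks the log2 ratio of the scaling steps (-0.40), close to the median of genes with a mean of at least 1 read per nt. Genes dense in only some tissues, such as Tff2, can lie far from it.

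Cells sorted from intestine differed from those from bladder in genes that mark position along the body. All 12 tested HOX genes of groups 9 to 13, which pattern the caudal body, were lower in intestine, and all 11 tested genes of groups 1 to 5 were higher. Contractile, ion channel, NOTCH and mural cell genes were mostly higher in intestine, whereas matrix genes were mostly lower. Genes of intestinal epithelium, enteric neurons and glia, and endothelium were mostly higher in the intestine libraries, and urothelial genes were mostly higher in the bladder libraries.

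Among the HOX genes, Hoxa11 (chromosome 6, 52219086 to 52222790) was at 1169 ± 44.0 in bladder and 0 in each intestine library, at least 426-fold lower. Hoxd13 was at 163 ± 9.29 in bladder and 0 in intestine, at least 59.5-fold lower. Hoxa13 was at 1071 ± 40.3 in bladder and 0.333 ± 0.577 in intestine. The antisense gene Hoxa11os, at least 187-fold lower in intestine, overlaps Hoxa11 (chromosome 6, 52221373 to 52226779), and their reads cannot be told apart without strand. Hoxb5 rose from 9 ± 3.61 in bladder to 514 ± 44.5 in intestine and Hoxa5 from 40 ± 11.5 to 481 ± 24.2. Of 6 HOX genes of groups 6 to 8, 3 were higher and 2 lower (4 and 2 adjusted over the list alone), with Hoxb6 at 10.3 ± 4.04 and 194 ± 7.57 and Hoxd8 at 420 ± 74.9 and 178 ± 7.77. Of 56 transcription factors of organ mesenchyme, 17 were higher and 29 lower (17 and 30 adjusted over the list alone). Tbx5, a T-box factor of heart, lung and forelimb, was at 352 ± 16.4 in bladder and 0 in intestine, at least 128-fold lower, and Tbx18 at 308 ± 46.5 and 0, at least 112-fold lower. Gata4 was at 74.7 ± 18.0 in bladder and 1176 ± 43.0 in intestine, and Nkx2-3, a homeobox factor of gut mesenchyme, at 1.67 ± 2.89 and 2750 ± 92.2.

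Of 36 contractile genes, 21 were higher in intestine and 5 lower, but 33 and 1 with the deposited scaling undone, while 24 of 26 fibroblast genes were lower. Lmod1, which nucleates actin filaments, was at 313 ± 47.7 in bladder and 2438 ± 162 in intestine, and the integrin Itga8 at 305 ± 34.3 and 3520.0 ± 458. Mylk, the myosin light chain kinase, was at 2028 ± 198 and 5570.0 ± 247. Cnn1 and Actg2 were lower by less, with log2 differences of -0.22 and -0.21, and both were near the upper end of read density. Of 65 ion channel and calcium handling genes, 40 were higher and 9 lower. Kcnq1 was at 24.3 ± 8.62 and 1726 ± 175, and Kcna5 at 90.7 ± 13.1 and 2985 ± 202, both potassium channels. Whether such RNA came from muscle cells or from other cells, whose markers were also higher in intestine, was not tested. Of 63 receptors for contractile agonists, 30 were higher and 13 lower (31 and 13 adjusted over the list alone), among them the sphingosine phosphate receptor S1pr3 at 686 ± 28.1 and 5256 ± 230.2 and the endothelin receptor Ednra at 594 ± 34.4 and 3002 ± 163. Of 18 NOTCH pathway genes, 13 were higher and 2 lower, with Notch3 at 298 ± 42.7 and 4693 ± 120 and its ligand Jag1 at 257 ± 49.2 and 2652 ± 254. Genes of vascular smooth muscle and pericytes moved with them: 16 of 21 were higher and 2 lower, with Mcam at 460 ± 78.7 and 4033 ± 236. Notch3 belongs to this list and to the NOTCH list.

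**Figure D3:**
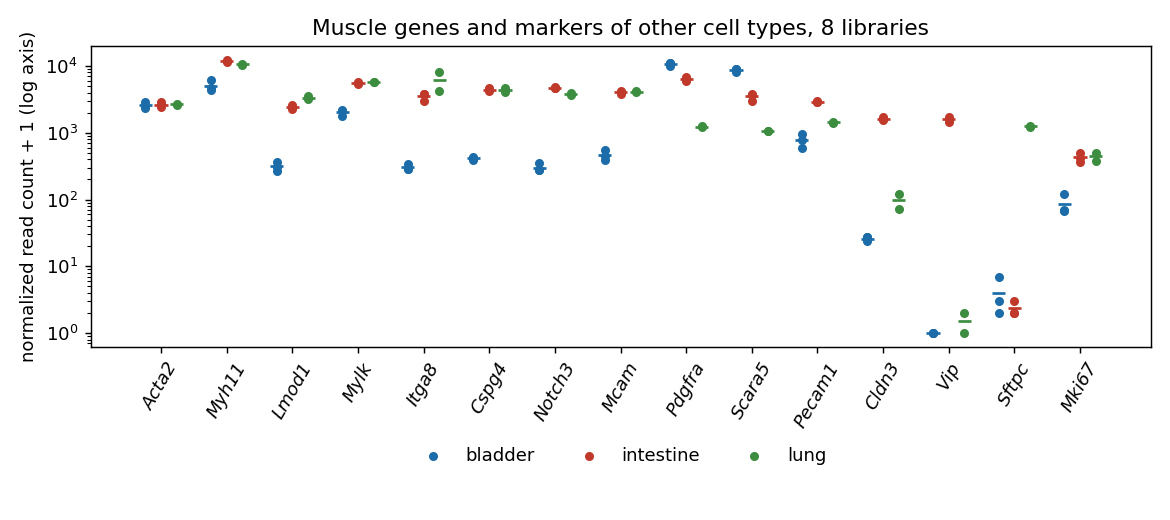
Normalized read count plus 1 (log axis) of muscle genes and markers of other cell types, with one point per library and a bar at the tissue mean. Acta2, near the upper end of read density, lies at close values in the 3 tissues, while Lmod1, Cspg4, Notch3 and Mcam lie lower in bladder and Pdgfra and Scara5 lie lower in lung.

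Of 43 collagen and interstitial matrix genes, 35 were lower in intestine and 2 higher (36 and 3 adjusted over the list alone), but 26 and 6 with the deposited scaling undone, and 16 members were near the upper end of read density. Fibroblast genes moved with them, 24 of 26 being lower, and a change in the share of fibroblast RNA was not separated from one within muscle cells. The proteoglycan Vcan was at 2583 ± 199 in bladder and 469 ± 74.5 in intestine, and Col12a1 at 3603 ± 410.1 and 875 ± 126. Of 32 elastic fibre and basement membrane genes, 22 were lower and 6 higher (23 and 6 adjusted over the list alone), but 13 and 8 with the deposited scaling undone, with the laminin chain Lama5 in the smaller group at 198 ± 18.9 and 1654 ± 188. Of 49 BMP and TGF-beta genes, 24 were lower and 8 higher, but 16 and 12 with the deposited scaling undone, with Bmp6 at 4995 ± 259 and 1919 ± 109.8. Of 14 hedgehog genes, 10 were lower and 2 higher, but 6 and 2 with the deposited scaling undone. Of 19 retinoid genes, 10 were lower and 5 higher, but 7 and 6 with the deposited scaling undone. Among the lists whose balance turned with the deposited scaling undone were 53 WNT genes (24 lower and 18 higher against 20 and 22), 35 FGF and PDGF genes (16 and 12 against 11 and 16) and 39 cytokine and complement genes (20 and 12, or 21 and 12 adjusted over the list alone, against 14 and 15). Among WNT antagonists, Wif1 was at 24.3 ± 3.79 in bladder and 1306 ± 67.8 in intestine, and Sfrp4 at 1807 ± 36.7 and 117 ± 6.43. Of 39 axon guidance genes, 16 were higher and 13 lower.

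Proliferation genes were higher in intestine for 26 of 31 members and lower for 0 (28 and 0 adjusted over the list alone), with the replication helicase gene Mcm2 at 396 ± 20.6 and 1084 ± 101 and the cycling marker Mki67 at 84.7 ± 30.6 and 426 ± 63.7. Of 36 immediate early and dissociation stress genes, 22 were lower and 2 higher (23 and 2 adjusted over the list alone), but 5 and 10 with the deposited scaling undone, and 16 members were near the upper end of read density. Of 62 oxidative phosphorylation genes, 9 were higher and 2 lower (7 and 1 adjusted over the list alone), but 56 and 0 with the deposited scaling undone, 15 and 1 with equal totals, and 6 and 7 with scaling from genes of low density. Of 23 glycolysis genes, 6 were higher and 9 lower (6 and 10 adjusted over the list alone), but 11 and 2 with the deposited scaling undone, 7 and 6 with equal totals and 8 and 8 with quantile normalization. Of 34 interferon response genes, 8 were higher and 14 lower, but 12 and 3 with it undone. Of 17 creatine and glycogen genes 5 were higher and 5 lower, but 9 and 3 with the deposited scaling undone. Of 19 nuclear receptors 8 were higher and 6 lower, but 5 and 5 with quantile normalization. Of 17 clock genes 9 were higher and 6 lower (10 and 6 adjusted over the list alone), but 6 and 6 with scaling from genes of low density. Vdr, the vitamin D receptor, was at 16.7 in bladder and 2386 ± 287 in intestine. Whether the RNA of Vdr and of the proliferation genes came from muscle cells or from other cells was not tested. Of 8 nuclear retained RNAs, 1 was higher and 4 lower (2 and 4 adjusted over the list alone), but 3 and 3 with the deposited scaling undone. Of 4 sex-linked genes 0 were higher and 2 lower, but 0 and 1 with the deposited scaling undone.

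Markers of other cell types also differed. Of 25 intestinal epithelium genes, 23 were higher in intestine and 1 lower, with the homeobox gene Cdx1 at 0 in bladder and 1481 ± 82.1 in intestine, at least 410-fold higher. Of 22 general epithelium genes, 17 were higher and 4 lower, the tight junction gene Cldn3 being at 25 ± 1.73 and 1628 ± 106. Of 27 enteric neuron and glia genes, 24 were higher and 0 lower, and the neuropeptide gene Vip was at 0 and 1595 ± 154, at least 441-fold higher. Of 22 endothelial genes, 20 were higher and 2 lower, with Vwf at 278 ± 25.7 and 3357 ± 516. Urothelium genes were lower for 16 of 20 and higher for 2, with the uroplakin gene Upk1a at 2129.7 ± 209 and 5 ± 2.65. Of 26 fibroblast genes, 24 were lower and 2 higher, but 16 and 2 with the deposited scaling undone and 13 and 3 with quantile normalization, 12 members being near the upper end of read density, and Pdgfra was at 10688 ± 654 and 6432 ± 487. Of 18 mesothelium genes, 10 were lower and 2 higher, but 7 and 4 with the deposited scaling undone. Leukocyte genes divided into 9 higher and 14 lower of 31, with the antibody chain gene Jchain at 2.33 ± 2.08 and 1871 ± 118 and the lysozyme gene Lyz2 at 2056 ± 409.7 and 492 ± 40.6. All 6 erythroid genes were higher, as were 6 of 12 genes of interstitial cells of Cajal with 2 lower. Of 9 adipocyte genes 5 were higher and 4 lower. Lung epithelium genes were higher for 6 of 20 and lower for 1, but for 5 and 6 with quantile normalization. Cardiac and skeletal muscle genes were higher for 7 and lower for 5 of 25, but for 4 and 9 with quantile normalization. Airway smooth muscle genes were higher for 4 and lower for 5 of 15, but for 7 and 4 with the deposited scaling undone.

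Across all genes, 5185 were higher in intestine than in bladder and 4210 lower. Of these, 3647 and 1568 had an absolute log2 difference of at least 1. In a fit without the lung libraries, 5574 were higher and 4627 lower. Among the genes of largest rise were Clca3b (at least 862-fold), Dmbt1 (3 ± 4.36 in bladder and 7757 ± 258 in intestine), Fcgbp (at least 782-fold), Chgb (at least 718-fold) and Alpi (at least 500.2-fold), genes of goblet, enteroendocrine and absorptive epithelium. The largest falls were in Cntn4, a neural adhesion gene (at least 1078-fold), Hoxa11, Hoxa13, Retnla (at least 279-fold), the cornified envelope gene Ivl (at least 228-fold) and Hoxa11os. The share of calls that were higher, 55.2%, became 81.2% with the deposited scaling undone and 41.7% with quantile normalization. With the scaling undone, 1926 of the 4210 lower genes stayed lower and 55 calls turned. With camera's preset correlation 55 of 126 list-by-pair tests passed over the 3 pairs, but 0 did with an estimated correlation (26 at an unadjusted p under 0.05, smallest adjusted p = 0.0846), and fry called 97.

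Cells sorted from lung also differed from those from bladder in HOX and contractile genes, and genes of lung epithelium and of cardiac and skeletal muscle were mostly higher in lung. All 12 HOX genes of groups 9 to 13 were lower in lung than in bladder, and 9 of 11 of groups 1 to 5 were higher. Contractile and mural cell genes were mostly higher in lung, as were genes of airway smooth muscle and of proliferation. Urothelial, fibroblast and mesothelial genes were mostly lower.

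Hoxa10 (chromosome 6, 52208177 to 52217834) was at 1712 ± 91.6 in bladder and 0 in lung, at least 677-fold lower, and Hoxa11 was at least 462-fold lower. Hoxb5 was at 9 ± 3.61 and 1074 ± 26.9, Hoxb4 at 5 ± 1 and 336 ± 120.2, and Hoxb6 at 10.3 ± 4.04 and 808.5 ± 89.8. Of 6 genes of groups 6 to 8, 3 were higher and 2 lower, Hoxd8 being at 420 ± 74.9 and 1.5 ± 0.707. Of 56 mesenchyme transcription factors, 17 were higher and 24 lower (18 and 26 adjusted over the list alone), but 21 and 18 with the deposited scaling undone. Pitx1, a homeobox factor, was at 1689 ± 139.6 and 3 ± 1.41.

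Of 36 contractile genes, 23 were higher in lung and 2 lower (24 and 3 adjusted over the list alone), while 25 of 26 fibroblast genes were lower, with Lmod1 at 313 ± 47.7 and 3326 ± 240.4 and the junctional protein gene Jph2 at 830 ± 12.5 and 3236.5 ± 92.6. Of 65 ion channel genes, 25 were higher and 18 lower (26 and 19 adjusted over the list alone), but 29 and 11 with the deposited scaling undone. Among them were the potassium channels Kcnk3 at 229 ± 43.9 and 3549.5 ± 326 and Kcnn3 at 2079 ± 129 and 41.5 ± 7.78. Of 63 agonist receptors, 19 were higher and 22 lower (20 and 24 adjusted over the list alone), but 25 and 17 with the scaling undone. The PACAP receptor Adcyap1r1 was at 3644 ± 218 and 93 ± 21.2 and the vasopressin receptor Avpr1a at 2527 ± 224 and 25.5 ± 6.36. Airway smooth muscle genes were higher for 10 of 15 and lower for 3, with Cdh4 at 168 ± 51.3 and 2954.5 ± 841. Mural genes were higher for 14 and lower for 2 of 21, with Notch3 at 298 ± 42.7 and 3819.5 ± 159. NOTCH genes were higher for 10 of 18 and lower for 1 (11 and 2 adjusted over the list alone). Cardiac and skeletal muscle genes were higher for 18 of 25 and lower for 2, among them the cardiac actin gene Actc1 at 47.7 ± 6.66 and 2329.5 ± 17.7 and the atrial light chain gene Myl7 at 14 ± 5 and 537 ± 45.3.

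Of 43 matrix genes, 31 were lower in lung and 4 higher (31 and 5 adjusted over the list alone), but 14 and 12 with the scaling undone and 17 and 8 with quantile normalization, beside the fall of fibroblast genes. Efemp1 was at 4300 ± 331.5 in bladder and 563 in lung, and Ltbp2, a latent TGF-beta binding protein, at 1163 ± 42.0 and 5995.5 ± 81.3. Of 32 elastic fibre genes, 22 were lower and 7 higher (23 and 7 adjusted over the list alone), but 12 and 10 with the scaling undone, with Npnt in the smaller group at 250.3 ± 37.0 and 4781 ± 1085. Of 14 hedgehog genes, 9 were lower and 3 higher, but 6 and 4 with the scaling undone, with Hhip, a hedgehog antagonist, at 2884 ± 199 and 7700.5 ± 1667. BMP genes were lower for 21 of 49 and higher for 13 (21 and 16 adjusted over the list alone), but for 10 and 26 with the scaling undone, 12 and 15 with quantile normalization and 16 and 16 with equal totals. WNT genes (24 lower, 13 higher of 53, or 24 and 14 adjusted over the list alone), axon guidance genes (21 and 12 of 39), cytokine genes (17 and 11 of 39, or 17 and 12 adjusted over the list alone) and interferon genes (17 and 3 of 34) turned to 15 and 19, 12 and 14, 14 and 17, and 2 and 8 with the scaling undone. FGF genes were higher for 12 of 35 and lower for 11, but for 22 and 6 with the scaling undone, with Fgf18 at 235 ± 12.2 and 1283 ± 199. Retinoid genes were higher for 3 and lower for 8 of 19, but for 5 and 5 with the scaling undone.

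Proliferation genes were higher for 29 of 31 and lower for 0, with the spindle gene Tpx2 at 127 ± 28.8 and 831 ± 259. Their share of the summed values, in ppm, was 597 ± 31.4 in bladder and 1554 and 2478.5 in the lung libraries, which therefore differed from each other. Immediate early and stress genes were lower for 29 of 36 and higher for 0 (31 and 0 adjusted over the list alone), but for 9 and 5 with the scaling undone. Among them were Fosb at 7417 ± 636 and 869.5 ± 251 and Atf3 at 4108 ± 241 and 825.5 ± 153. Oxidative phosphorylation genes were higher for 4 of 62 and lower for 6 (1 and 4 adjusted over the list alone), but for 55 and 0 with the scaling undone, 7 and 3 with quantile normalization and 12 and 1 with equal totals. Clock genes were higher for 1 of 17 and lower for 3, but for 6 and 1 with the scaling undone, and nuclear receptors for 5 and 7 of 19 (6 and 8 adjusted over the list alone), but for 6 and 5. Glycolysis genes were higher for 7 and lower for 6 of 23, but for 12 and 1 with the scaling undone. Creatine genes were higher for 8 and lower for 4 of 17, but for 11 and 2 with the scaling undone. Sex-linked genes were higher for 0 and lower for 3 of 4, but for 0 and 1 with it undone. Nuclear retained RNAs were higher for 0 and lower for 6 of 8 (0 and 7 adjusted over the list alone), but for 1 and 3 with the scaling undone.

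Lung epithelium genes were higher in lung for 16 of 20 and lower for 1 (16 and 2 adjusted over the list alone), with the surfactant gene Sftpc at 3 ± 2.65 and 1253 ± 26.9. General epithelium genes were lower for 20 of 22 and higher for 2, the keratin gene Krt5 being at 329 ± 72.8 and 0, at least 130.1-fold lower. Urothelium genes were lower for 18 of 20 and higher for 0, fibroblast genes for 25 and 1 of 26, and mesothelium genes for 15 and 0 of 18 (16 and 0 adjusted over the list alone). Pdgfra was at 10688 ± 654 and 1223.5 ± 29.0 and the fibroblast scavenger receptor gene Scara5 at 8705 ± 604 and 1066 ± 4.24. Endothelial genes were higher for 12 of 22 and lower for 5 (13 and 5 adjusted over the list alone). Leukocyte genes were higher for 10 of 31 and lower for 14 (10 and 16 adjusted over the list alone), with the macrophage gene C1qa at 865 ± 303 and 96 ± 7.07. Enteric genes were higher for 5 and lower for 9 of 27, and intestinal epithelium genes for 0 and 3 of 25. Genes of interstitial cells of Cajal were higher for 6 and lower for 3 of 12, and erythroid genes for 5 and 1 of 6. Adipocyte genes were higher for 3 and lower for 4 of 9, but for 4 and 3 with the scaling undone.

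In all, 3466 genes were higher in lung than in bladder and 3952 lower. Of these, 2021 and 2063 had an absolute log2 difference of at least 1. In a fit without the intestine libraries, 2503 were higher and 3143 lower. Sftpa1 (at least 355-fold), Sost (2 ± 2.65 and 1656 ± 399), Egfem1 (at least 134.5-fold), Sftpd (at least 102-fold), Sftpc and Mylk4 had the largest rises. The largest falls were in Hoxa10, Hoxa11, Hoxa13, Upk3a (1460.0 ± 241 and 1.5 ± 2.12), Sbp (at least 265-fold) and Ivl (at least 248-fold). The share that was higher, 46.7%, became 80.8% with the deposited scaling undone and 58.5% with equal totals. With the scaling undone 143 calls turned, and 1896 of the 3952 lower genes stayed lower.

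Lung and intestine differed in regional factors, matrix, channels and the markers of other cells. Tbx5 and Tbx4 were higher in lung, and Nkx2-3 and Gata4 were lower. Of airway smooth muscle, cardiac and BMP genes more were higher than lower in lung. Of ion channel, general and intestinal epithelium, enteric and endothelial genes more were lower than higher in lung.

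Acta2, Cspg4 and Myh11 did not pass the test in this pair (limma, Benjamini-Hochberg adjusted p = 0.899, 0.978 and 0.279), which does not show equal expression, since Acta2 and Myh11 were near the upper end of read density. Tbx5 (chromosome 5, 119970733 to 120023284) was at 0 in intestine and 1259 ± 70.7 in lung, at least 459-fold higher, and Tbx4 at 45 ± 24.6 and 3696 ± 45.3. Of 56 mesenchyme transcription factors, 23 were higher in lung and 18 lower (23 and 19 adjusted over the list alone). HOX genes of groups 1 to 5 were higher for 4 of 11 and lower for 2 (5 and 2 adjusted over the list alone). Those of groups 6 to 8 were higher for 2 and lower for 2 of 6 (3 and 2 adjusted over the list alone), but for 4 and 2 with quantile normalization, and those of groups 9 to 13 for 0 and 2 of 12. Hoxc5 was at 189.7 ± 1.15 in intestine and 6.5 ± 2.12 in lung. Contractile genes were higher for 12 of 36 and lower for 3 (12 and 4 adjusted over the list alone), with the small heat shock protein gene Hspb6 at 848 ± 138 and 2073.5 ± 36.1. Airway smooth muscle genes were higher for 10 of 15 and lower for 2. Cardiac genes were higher for 13 and lower for 2 of 25 (15 and 2 adjusted over the list alone), with the troponin gene Tnnt2 at 245 ± 5.57 and 1293 ± 35.4. Mural genes were higher for 1 of 21 and lower for 7, with Rgs5, a regulator of G protein signalling, at 4203 ± 189 and 626.5 ± 276.

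Ion channel genes were lower in lung for 31 of 65 and higher for 8, with the calcium channel Cacna1h at 1116 ± 73.0 and 91.5 ± 0.707. Agonist receptors were lower for 30 and higher for 13 of 63 (33 and 13 adjusted over the list alone), with the adrenergic receptor Adra2a at 658 ± 7.02 and 36 ± 5.66. Matrix genes were higher for 17 of 43 and lower for 8, with Ltbp2 at 519.7 ± 34.4 and 5995.5 ± 81.3 and Spp1 at 146 ± 39.0 and 2206.5 ± 115. BMP genes were higher for 22 of 49 and lower for 8 (22 and 10 adjusted over the list alone), the activin antagonist Fst being at 112 ± 5.77 and 2172.5 ± 699. Elastic fibre genes were higher for 4 and lower for 10 of 32, but for 7 and 8 with the scaling undone. NOTCH genes were higher for 3 and lower for 8 of 18 (3 and 9 adjusted over the list alone). FGF genes were higher for 12 and lower for 9 of 35, and hedgehog genes for 4 and 4 of 14, but for 4 and 2 with the scaling undone. WNT genes were higher for 15 and lower for 18 of 53 (16 and 21 adjusted over the list alone), but for 19 and 17 with quantile normalization and 16 and 16 with the scaling undone. Axon guidance genes were higher for 12 and lower for 14 of 39 (12 and 16 adjusted over the list alone), but for 12 and 11 with the scaling undone.

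Proliferation genes were higher in lung for 10 of 31 and lower for 0, but for 16 and 0 with quantile normalization. Immediate early genes were higher for 1 and lower for 16 of 36. Cytokine genes were higher for 14 and lower for 17 of 39, but for 15 and 15 with the scaling undone or quantile normalization. Interferon genes were higher for 3 and lower for 10 of 34. Retinoid genes were higher for 5 and lower for 8 of 19, nuclear receptors for 4 and 9 of 19 and clock genes for 1 and 7 of 17. Oxidative phosphorylation genes were higher for 1 of 62 and lower for 4 (0 and 0 adjusted over the list alone), but for 1 and 0 with the scaling undone. Glycolysis genes were higher for 5 and lower for 5 of 23, but for 6 and 5 with quantile normalization, and creatine genes for 6 and 2 of 17. Nuclear retained RNAs were higher for 0 and lower for 3 of 8 (1 and 3 adjusted over the list alone), but for 3 and 3 with quantile normalization. Sex-linked genes were higher for 0 and lower for 0 of 4, but for 0 and 2 with it. Intestinal epithelium genes were lower for 24 of 25 and higher for 0, and general epithelium genes for 19 and 0 of 22. Enteric genes were lower for 23 and higher for 0 of 27, and endothelial genes for 16 and 0 of 22 (17 and 0 adjusted over the list alone), the lymphatic gene Prox1 being at 566 ± 149 and 9 ± 1.41. Lung epithelium genes were higher for 15 of 20 and lower for 3. Leukocyte genes were higher for 3 and lower for 13 of 31 (3 and 17 adjusted over the list alone), but for 7 and 7 with quantile normalization. Fibroblast genes were higher for 3 and lower for 12 of 26, and mesothelium genes for 0 and 6 of 18. Adipocyte genes were higher for 1 and lower for 3 of 9, and genes of interstitial cells of Cajal for 2 and 4 of 12, but for 4 and 4 with quantile normalization. Erythroid genes were higher for 0 and lower for 3 of 6 (0 and 6 adjusted over the list alone). Urothelium genes were higher for 5 and lower for 7 of 20, but for 6 and 5 with quantile normalization.

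In this pair 2882 genes were higher in lung and 4275 lower, 1101 and 3131 of them with an absolute log2 difference of at least 1. In a fit without the bladder libraries, 2200 were higher and 3791 lower. After Tbx5 and Sftpa1 (0.333 ± 0.577 in intestine and 1283 ± 146 in lung), the largest rises were in Sftpc, Sost, Egfem1 (at least 177-fold) and Chil3 (at least 88.5-fold). The largest falls were in Cps1 (at least 2110-fold), Dmbt1, Adamdec1 (at least 1694-fold), Clca3b (at least 1232-fold), Olfm4 (4124 ± 201 in intestine and 0.5 ± 0.707 in lung) and Fcgbp (at least 1117-fold). The share that was higher, 40.3%, became 50.9% with the deposited scaling undone and 59.5% with quantile normalization.

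Genes higher in a tissue than in both others numbered 1865 in bladder, 2257 in intestine and 554 in lung. The bladder set was led by Hoxa11, Hoxa13, Ivl, Hoxa11os, Sbp, Upk1a, Krt5 and Snx31, which include caudal HOX genes and genes of urothelium. Clca3b, Dmbt1, Fcgbp, Olfm4, Cdx1, Nkx2-3 and Cdhr5 were among the leading genes of the intestine set. The lung set was led by Sftpa1, Sost, Egfem1, Sftpc, Chil3, Myh6, Sftpb and Ccdc42, with the surfactant gene Sftpb at 263 ± 42.4 in lung and the atrial myosin gene Myh6 at 588 ± 437. The lung count was 293 without lung replicate 2, 343 without intestine replicate 2 and 332 without intestine replicate 3, and with the deposited scaling undone it was 1551 and the bladder count 409.

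**Figure D4:**
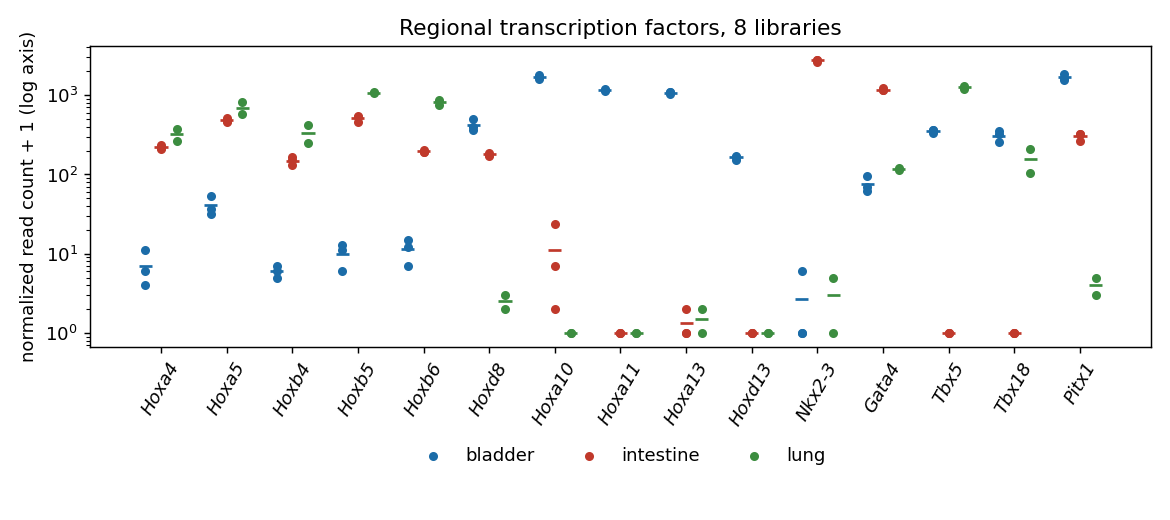
Normalized read count plus 1 (log axis) of HOX genes and other regional transcription factors, with one point per library and a bar at the tissue mean. Hoxa10, Hoxa11, Hoxa13 and Hoxd13 lie near 0 in intestine and lung, and Nkx2-3 lies near 0 in bladder and lung.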

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

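The deposited scaling undone, equal totals, quantile normalization, scaling from genes of low density and leaving out the densest genes were chosen after seeing the data. Of 248 counts under alternatives, 225 were within 1.5 times the value reported. The single genes followed were Acta2, Cspg4 and Myh11, and those picked in these data for the largest fold changes or enrichment. Differences that large hardly weaken under such changes, so the outcome does not carry over to other genes. Of 748 alternative values for 68 gene-by-pair results, 745 were the same, 0 were weaker or reversed, and 3 newly passed the threshold. These were Acta2 for intestine and lung minus bladder with the deposited scaling undone (0.42 and 0.56), and Myh11 for lung minus intestine without bladder replicate 1, at an unchanged -0.17. A fold threshold of 1 on the log2 scale asks for larger changes by construction and left 2307 genes higher and 685 lower for intestine minus bladder, 916 and 1053 for lung minus bladder, and 401 and 2011 for lung minus intestine, 6918 genes differing among the tissues, and 206, 1208 and 89 enriched in bladder, intestine and lung. Undoing the deposited scaling, which removes the correction for depth, gave 8326 and 1926 for intestine minus bladder and 7956 and 1896 for lung minus bladder, with 409 enriched in bladder and 1551 in lung. Quantile normalization gave 5172 genes higher for lung minus intestine and 847 enriched in lung, and the cause was not tested. Gene lists past the threshold numbered 0 with an estimated correlation (26 at an unadjusted p under 0.05) and 97 with fry, against 55. The 0 and the 55 came from camera with an estimated and with a preset correlation between genes of a list. Why they differ, and the cause of the 97, was not tested. For intestine minus bladder a wrong split of the libraries, with 0 genes called, still gave 21 lists against 22 for the real one. Every wrong split mixed the tissues unevenly, so its groups still held part of the tissue difference. The 21 lists are therefore not a count free of tissue. The number of lists past the preset threshold alone does not measure how far the tissues differ.

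Without each library in turn, genes higher and lower ranged from 4531 to 5596 and 3547 to 4643 for intestine minus bladder, 2769 to 3516 and 3375 to 4222 for lung minus bladder, and 2117 to 3234 and 3507 to 4646 for lung minus intestine. Genes differing among the tissues ranged from 10076 to 12281, those enriched in bladder from 1308 to 1913, in intestine from 1805 to 2308 and in lung from 293 to 557, and lists from 52 to 58. The lowest lung value was without lung replicate 2, and 343 and 332 were left without intestine replicates 2 and 3. Where lung was left with 1 library, it was assumed to vary like the other tissues. Whether the replicate numbers pair the libraries is not given in the labels. Residuals of 7 same-numbered pairs correlated at -0.03 to 0.06 and of 14 others at -0.07 to 0.07. That gave no sign of pairing, but with 3 or 2 libraries per tissue it cannot exclude it. With a replicate block 5058 and 3982 genes were called for intestine minus bladder, 3115 and 3671 for lung minus bladder, 2474 and 4022 for lung minus intestine, 10758 among the tissues, 1567, 2118 and 412 as enriched, and 56 lists, with 3 list calls changed. DESeq2 and its RLE scaling were not run, since the values are not counts and already carry scaling of that kind. Depth limits what 0 means to the floor of 2.47 to 3.81 in normalized value.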

Other observations

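All tests of the patterns below were chosen after the results were seen, and the counts of other splits were planned before. The genes of this and the next paragraph were singled out after their values were seen. The intestine libraries also held transcripts known from stomach glands. Which part of the gut was taken is not given in the sources used here, so tissue taken along with the sample and other glands stay open as their origin. Muc6, the mucin of gland mucous cells, was at 10282 ± 446 in intestine against 218 ± 124 in bladder and 6 ± 5.66 in lung. Pgc, a pepsinogen gene, was at 2152 ± 74.2, 29.3 ± 17.4 and 24.5 ± 9.19, and Atp4a, the proton pump of parietal cells, at 908 ± 74.5, 0.667 ± 0.577 and 2.5 ± 3.54. Tff2, a trefoil factor of the same mucous cells, was at 1306 ± 60.9, 326 ± 113 and 5 ± 0. Defa24, a Paneth cell defensin gene of a multigene family whose reads can be shared, was at 629.7 ± 31.6 in intestine.

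Tagln, a smooth muscle actin-binding protein gene, was at 168 ± 17.8 in bladder, 314 ± 33.6 in intestine and 480.0 ± 7.07 in lung, with 0.0624 to 0.291 reads per nt, far below the upper end of read density. Tnni3, the cardiac troponin I gene, was at 17.7 ± 2.52 in bladder, 3 ± 1.73 in intestine and 355 ± 106 in lung, whereas Ryr2, the cardiac ryanodine receptor, was at 8.67 ± 9.07, 257 ± 12.5 and 138 ± 21.2. Pln, a brake of the calcium pump, was at 35.7 ± 6.66, 777 ± 69.7 and 52.5 ± 33.2. The atrial peptide gene Nppa was at 0.333 ± 0.577, 0 ± 0 and 20.5 ± 14.8.

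Abundant genes were lower in intestine and lung than in bladder, with medians of -0.40 and -0.42 over 339 genes near the upper end of read density, where B2m had 1606 to 1647 reads in each library. A ceiling on reads per nt, carried into the scaled values, may account for part of this. Removal of repeated reads by position would give one (not tested, Picard being named without a role). With the scaling undone the medians were 1e-04 and 0.0895, against 0.3132 and 0.5099 for genes of 0.2 to 0.4 reads per nt. That restates how close the dense genes lay to the scaling shift. Within tissues, depth was taken as the inverse ratio of the scaling steps. The reads of the dense genes followed it with a slope of 0.279 over 7 pairs of libraries, which share libraries. For genes of 0.2 to 0.4 reads per nt it was 0.877, but the steps centre the median gene, so a slope near 1 was likely there. Dense genes moved the other way in the lung pair, by 0.0225 at a log2 depth ratio of -0.0745. The ratio of variance to mean of their bladder reads was 3.71, above the value under 1 that a hard ceiling predicts, although below the 7.76 of those less dense genes, and it was 0.882 in intestine. After scaling to equal totals it was 4.77 against 3.07 in bladder and 5.33 against 3.44 in intestine, but scaling also adds spread to genes that do not follow depth, so this ratio leaves the ceiling undecided. Higher expression in bladder stays open for the 257 called lower in intestine and the 251 called lower in lung, while 20 were called higher in each pair. With the scaling undone 92 and 59 stayed lower. In the others, and in genes not called, saturation may hide a difference.

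Genes of the intestinal and general epithelium lists and of enteric neurons and glia were mostly higher in the intestine libraries, whereas urothelium genes were mostly higher in bladder. A lower share of smooth muscle cells that raised all other cell types alike does not account for it. Over members with a mean under 1 read per nt, medians were 2.19 for epithelium, 1.75 for endothelium, -0.58 for leukocytes and -0.62 for fibroblasts. They lay apart by 2.81, more than their largest median absolute deviation of 2.34. A lower share that raised some cell types more than others would also set the medians apart. At unchanged expression per muscle cell it would lower contractile genes, yet 21 of 36 were higher in intestine and 5 lower. Over the 30 with a mean under 1 read per nt, the median was 0.73, or 1.12 with the scaling undone. These values argue against a lower share at unchanged expression per cell. A lower share offset by higher expression per cell stays open. Of 25 intestinal epithelium genes 23 were higher in intestine than in both other tissues, a count that restates the pattern and decides between no explanations. RNA of other intestinal cells in the sorted fraction, which the sort was meant to leave out, and expression in the sorted cells themselves both stay open.

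Cspg4 and mural cell genes were lower in bladder than in intestine and lung. Scaling does not account for the log2 difference of Cspg4, the smallest over 6 scalings and both pairs being 3.315. That outcome was nearly fixed, since the scalings moved the median tested gene by far less. The median of the mural list was 2.83 for intestine minus bladder and 2.00 for lung minus bladder. With quantile normalization it was 2.38 and 1.84. Of the 20 other members of the list, 15 were higher in intestine and 13 in lung, counts that restate the pattern. Pericytes or vascular smooth muscle cells in the intestine and lung fractions, which the sort was meant to leave out since the labels call the cells non-vascular, and a difference in the non-vascular cells both stay open.

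Other splits of the libraries gave fewer calls. For intestine minus bladder the real split gave 9395 genes and the highest of the other splits 0, and for gene lists 22 against 21, but 10 splits are too few for a share under 0.05, the real one being 1 of 10. For genes differing among the 3 tissues, 1 of 100 splits drawn (of 280 possible), the real one, reached 11390. The highest other gave 4295, so a random split of these libraries does not account for that count. Nothing in the labels says that the libraries came from separate mice, so differences between animals or sorts stay open.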
